A study of Mus musculus with 9 samples.

How the data were processed

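RNA was measured in epithelial cells of the trachea of KRT5-GFP transgenic mice, in which a green fluorescent protein (GFP) marks cells with an active keratin 5 promoter. Per the labels' protocols, cells were sorted by fluorescence-activated cell sorting on GFP and on binding of the lectin GSI-A3B, RNA was purified with a column kit for small samples, and amplified, biotin-labelled cDNA was hybridised to Affymetrix mouse expression arrays. The labels describe 3 gates with 3 biological replicates each, so 9 arrays in all. The GFP+ lectin+ gate is called the GFP+ gate here, the GFP- lectin+ gate is called the lectin-only gate, and the GFP- lectin- gate, which the labels name columnar epithelium, is called the columnar gate. Arrays are named by gate and by the replicate number in the labels.

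The deposited values were log2 probe set signals, 1 column per array, which the authors made with RMA (background correction, quantile normalization and summary of probes), per the submitters' processing notes. The software and its version, and any filter, were not given in the sources used here. That the values are log2 was checked on their range. Medians lay between 4.91 and 5.16 on 8 arrays and at 5.44 on replicate 3 of the lectin-only gate, so the arrays did not share 1 distribution and the deposited scaling was tested against others. The table held 45101 probe sets, of which 64 were control probe sets. The platform annotation given with the data paired 34945 probe sets with 1 gene symbol, 932 with several and 9160 with none. Symbols of 34741 probe sets were brought up to date through a RefSeq gene table. Probe sets with several symbols or none, and control probe sets, were left out of gene counts.

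Each gene was represented by its probe set with the highest mean over the 9 arrays, which gave 18193 genes, 9010 of them with several probe sets to choose from. Of the called results for named genes with several probe sets, 248 in number, 0 had another probe set of the same gene called in the opposite direction. That does not mean that all probe sets of a gene were called. In GFP+ against columnar, all 4 of Tgfbi were. Other probe sets of Dsc3 and Dcn lay at 0.65 and 0.36 there and were not called, and 1 of Dnah9 lay at 0.19 in lectin-only against columnar. Group means were fitted to all 9 arrays at once with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust), with 6 residual degrees of freedom and a prior of 3.46. P-values were adjusted over the 18193 genes by the Benjamini-Hochberg method for each comparison. A gene was called where the adjusted p was under 0.05 and the absolute log2 difference was at least 1. Errors of log2 differences are limma standard errors (SE), and errors of levels are standard deviations (SD) over 3 arrays. The number of arrays limits the precision: the median SE over all genes was 0.24 on the log2 scale. All adjusted p-values for genes are from limma.

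A background level of 3.56 on the log2 scale was set as the 95th percentile of 80 probe sets of olfactory and vomeronasal receptors, which stood for genes silent in these cells. Where a gene was under this level on all 3 arrays of a gate, the difference from that gate is a bound: the mean of the brighter gate was set against the dim gate's mean of, per array, the higher of the background level and the gene's own signal. Such values are printed as at least N-fold. Differences are printed as fitted where the mean of a gate, but not each of its arrays, lay under this level. This held for 25 called results of named genes, and with dim arrays set to the level their differences would be smaller by a median of 0.33 and at most 1.04 on the log2 scale.

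The comparisons, the test, the threshold, the rule for named genes, the 28 gene lists and most alternatives were fixed before the data were examined. The lists cover basal, ciliated, club and other secretory, neuroendocrine, brush, ionocyte, submucosal gland and squamous (hillock) cells, and endothelial cells, leukocytes, fibroblasts, smooth muscle or myoepithelial cells, cartilage, Schwann cells and erythroid cells. They also cover hemidesmosome and basement membrane, detoxification of foreign compounds, Notch and Wnt signalling, growth factors, factors of epithelial-mesenchymal transition, cell cycle, immediate early genes, glycolysis, oxidative phosphorylation, tight junctions, ion and water transport, and cytokines. The growth factor list holds genes of the EGF, FGF, IGF, PDGF, VEGF, TGF-beta and BMP families. Of 593 list memberships, 563 were measured. Per comparison, the named genes are the 10 largest increases and 10 largest decreases among called genes whose arrays do not overlap between the gates, leaving out clone and model names. Up to 4 called members of largest change per list were added, or up to 2 members where few or none were called. Krt5, Krt14, Trp63, Ngfr, Pdpn, Scgb1a1 and Foxj1 were always named. Genes shared by both lectin-binding gates, or set apart in the lectin-only gate, contributed the 10 largest in each direction. Within that rule, genes whose call held with each array left out were preferred as examples. The keratin 5 promoter set the GFP gate and the product of Ggta1 is bound by the lectin, so both would check the sort only. Ggta1 was not analysed here.

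Lists were tested with camera in limma, which compares a list with all other genes, at a preset correlation of 0.01 between genes. Its p-values were adjusted over the 84 tests of 28 lists and 3 comparisons. The estimated correlation and fry, which tests whether the genes of a list move one way on balance, were run beside it. With an estimated correlation, 2, 3 and 3 lists were called for the GFP+ against columnar, lectin-only against columnar and GFP+ against lectin-only comparisons, where the preset correlation called 18, 16 and 16. Those that held were basal cells and hemidesmosome and basement membrane in all 3 comparisons, and endothelial cells in both comparisons with the lectin-only gate. Correlation between genes is not the whole reason for the weaker results with that setting. The hemidesmosome list had an estimate of -0.021, under the preset value, and its adjusted p rose too. So did that of the endothelial list, with an estimate of 0.0023. A higher adjusted p with that setting therefore does not by itself show correlation between the genes of a list. Fry called 17, 17 and 14 lists, which included 16, 15 and 13 of those called by camera. Calls lost with fry were leukocytes and smooth muscle in GFP+ against columnar, detoxification in lectin-only against columnar, and Wnt, growth factors and cell cycle in GFP+ against lectin-only. Calls gained were Notch in both comparisons with the columnar gate, immediate early genes in lectin-only against columnar and detoxification in GFP+ against lectin-only. Counts of list members are given over all genes tested and, separately, adjusted over the list alone. Overlaps of lists with gene sets were tested with Fisher's exact test, one-sided, adjusted over 84 tests. Because 2 comparisons share the columnar arrays, 100 simulations of all 9 arrays without differences between gates were run. Shared calls were counted in 20 of them. For the genes set apart, whose comparisons share the lectin-only arrays, 20 simulations of unchanged groups and 20 with each gene's lectin-only mean held between those of the other gates were added after the results were seen.

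The fit was tested on simulated data with the real means and spreads of 18193 genes, 200 of them changed. For GFP+ against columnar, 98.4% of changes of 3 on the log2 scale, 88.5% of changes of 2 and 36.4% of changes of 1 passed an adjusted p of 0.05, with 6 false calls among 17993 unchanged genes. For lectin-only against columnar, 98.4%, 93.2% and 35.9% passed, with 7 unchanged genes past that p, and 6 with the fold minimum as well. For GFP+ against lectin-only, 97.1%, 96.8% and 25.4% passed, with 10 false calls.

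Alternatives were a replicate block, a fit of only the 2 gates compared, arrays centred on their medians, a further quantile normalization, a filter on dim genes, means over a gene's probe sets, removal of probe sets marked s, x or a, probe sets in place of genes, a trended and robust prior, array weights, 3 other thresholds and each array left out. Centring together with leaving out replicate 3 of the lectin-only gate was added after that array's shift was seen. No array was left out of the main values, and no pair of the 36 pairs of arrays held identical values. Plots were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.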

Results

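Gene expression was measured on 9 arrays in 3 populations of cells sorted from the mouse tracheal epithelium, with 3 biological replicates in each. The first population carried the keratin 5 reporter and bound the lectin (GFP+ gate), the second bound the lectin without detectable reporter (lectin-only gate), and the third had neither mark (columnar gate). The labels call both lectin-binding populations basal cells. Signals of 18193 genes were compared on the log2 scale. Between 65.3% and 66.3% of probe sets lay above the background level on 8 arrays, and 73.0% did on replicate 3 of the lectin-only gate. Correlations across probe sets, which are not independent replicates, were between 0.975 and 0.987 within a gate and between 0.952 and 0.985 between gates. Each difference below rests on 3 arrays per gate, and its error is the limma SE unless an SD is named.

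Krt5 and Trp63 separated both lectin-binding gates from the columnar gate, while the test did not call Krt5 between the GFP+ and the lectin-only gate. Krt5, whose promoter drives the reporter and which therefore checks the sort only, had a log2 signal of 13.44 ± 0.01 (SD, n = 3) in the GFP+ gate, 12.88 ± 0.15 in the lectin-only gate and 7.96 ± 1.12 in the columnar gate. The GFP+ and lectin-only gates differed in Krt5 by 0.55 ± 0.45 (adjusted p = 0.663), less than the test could separate. That SE is pooled over all 3 gates, so it includes the wide columnar spread (SD 1.12). The difference was larger than the SD of either gate compared, so a difference in Krt5 between them is not excluded. Trp63, a transcription factor of basal cells, had signals of 13.06 ± 0.13 (SD), 11.94 ± 0.14 and 7.62 ± 0.32 in the same order. Scgb1a1, the secretoglobin of club cells, had signals of 13.64 ± 0.13 (SD), 13.69 ± 0.07 and 13.74 ± 0.11, and no pair of gates differed by the test. Pdpn, a surface glycoprotein used to mark basal cells, lay at 13.14 ± 0.08 (SD), 12.72 ± 0.30 and 12.71 ± 0.07, and its difference of 0.43 ± 0.18 between the GFP+ and columnar gates did not pass (adjusted p = 0.177).

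**Figure D1:**
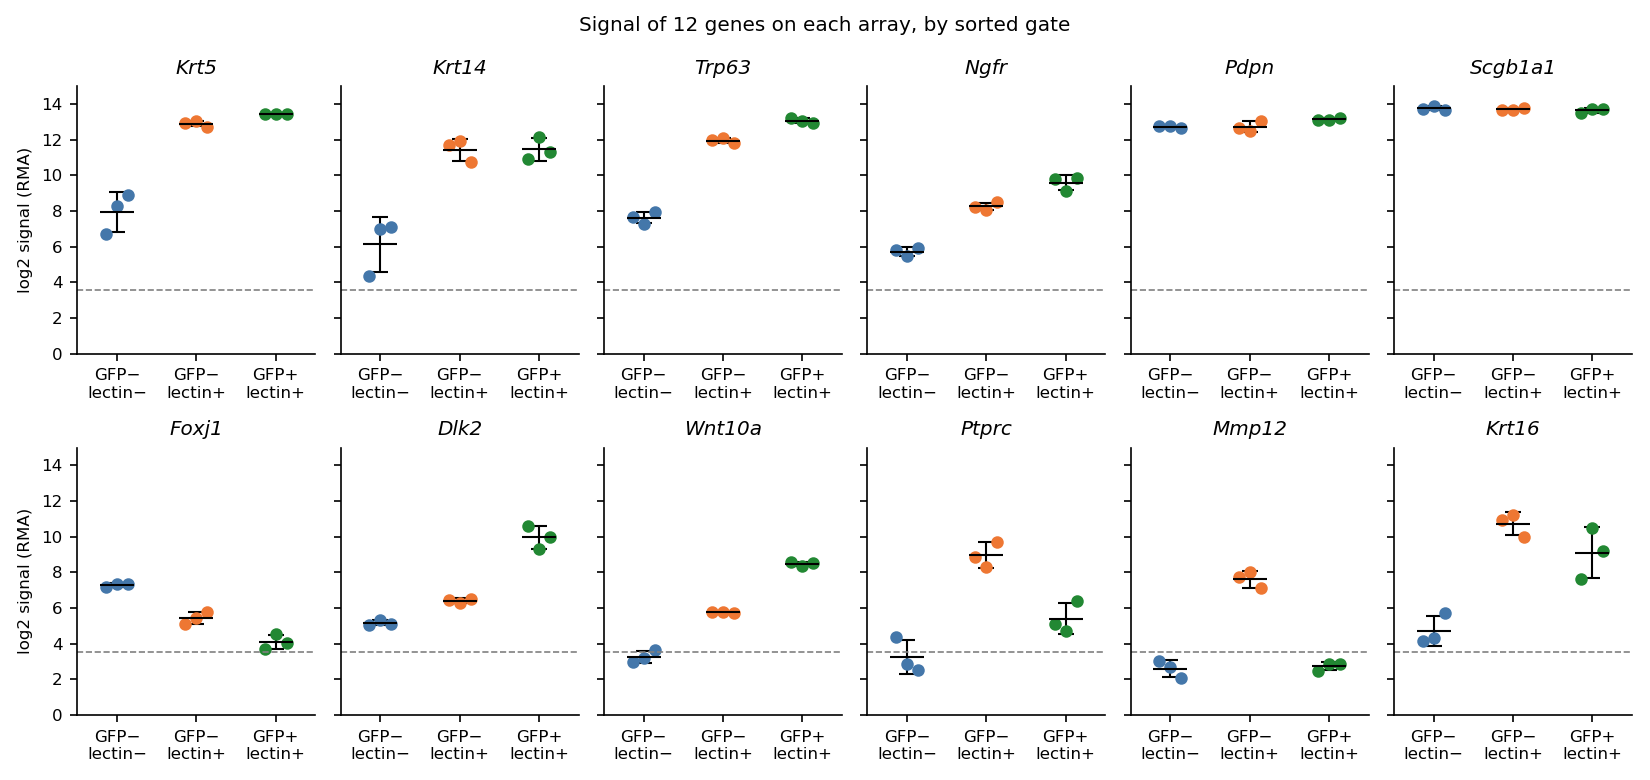
Log2 RMA signal (vertical axis) of 12 genes on each array (points), by gate (horizontal axis), with the mean and SD of 3 arrays (bars) and the background level of 3.56 (dashed line). Trp63 had means of 7.62, 11.94 and 13.06 from the columnar to the GFP+ gate, Scgb1a1 lay between 13.64 and 13.74 in all gates, and Mmp12 had a mean of 7.61 in the lectin-only gate against 2.61 and 2.74 in the others.

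The GFP+ gate was compared with the columnar gate to ask which genes distinguish basal cells from the columnar epithelium. The largest increases in the GFP+ gate included Col17a1, the hemidesmosomal collagen, at 128-fold (SE 0.43 on the log2 scale, adjusted p = 1.4e-05), the surface protein Cd109 at a log2 difference of 6.64 ± 0.23, the matrix protein Tgfbi at 6.57 ± 0.24 and the zinc finger protein Bnc1 at 6.27 ± 0.24. Vsnl1 (6.61 ± 0.40), Ccdc3 (6.40 ± 0.27), the desmosomal cadherin Dsc3 (5.96 ± 0.34) and the carboxylesterases Ces2f (5.96 ± 0.37) and Ces2b (5.93 ± 0.64) were also among them. The largest decreases included Retnla, a secreted resistin-like protein, at -5.49 ± 0.56, and Ldb3 at -4.96 ± 0.61, the sulfotransferase Sult1c1 at -4.92 ± 0.55 and Tmem212 at -4.89 ± 0.79. Thyroglobulin, Tg, was lower by the test at -5.61 ± 1.42 (adjusted p = 0.027), but its call was lost without columnar replicate 3 (-5.70), GFP+ replicate 2 (-5.04) or GFP+ replicate 3 (-5.14). In all, 2038 genes were called, 1069 higher and 969 lower in the GFP+ gate, and 208 and 177 of them differed by at least 8-fold. The split was 1004 higher and 1107 lower with arrays centred on their medians, and 1029 and 1042 after a further quantile normalization. The median SE of called genes was 0.30 on the log2 scale.

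Of the 20 measured genes of the basal cell list, 17 were higher in the GFP+ gate and 3 did not pass. The basal list had a camera adjusted p = 4.15e-24, and adjusted p = 0.0074 with an estimated correlation. The count was also 17 when adjusted over the list alone. They included Snai2, a zinc finger transcription factor, at 5.84 ± 0.30, the Notch ligand Jag2 at 5.50 ± 0.22, Krt14 at 5.33 ± 0.68 and the nerve growth factor receptor Ngfr at 3.86 ± 0.24. Ngfr, Pdpn, Snai2, Cd109 and Dlk2 are among genes that work on sorted tracheal cells of this kind put forward as basal cell markers, so this list is not independent evidence of its direction. Of 19 genes of hemidesmosomes and basement membrane, 11 were higher (11 adjusted over the list alone), among them the laminin chain Lamb3 at 5.82 ± 0.32 and the basement membrane collagen Col4a2 at 4.42 ± 0.49 (3.38 with dim arrays set to the background level). The hemidesmosome list had a camera adjusted p = 8.54e-12, and adjusted p = 0.0074 with an estimated correlation. Of 19 squamous (hillock) genes, 12 were higher (15 adjusted over the list alone), among them Krt16 at 4.39 ± 0.68 and the transglutaminase Tgm1 at 3.54 ± 0.45. The squamous list had a camera adjusted p = 1.62e-09, but adjusted p = 0.138 with an estimated correlation. The squamous count fell to 6 without columnar replicate 1 or GFP+ replicate 2, and to 5 without columnar replicate 2 or GFP+ replicate 3.

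In the lists of ciliated, secretory, gland, brush and neuroendocrine cells, the genes called over all genes tested were lower in the GFP+ gate. After a further quantile normalization, without columnar replicate 3 or without lectin-only replicate 2, 1 ciliated gene was called higher. Of 39 measured ciliated cell genes, 28 were lower (28 adjusted over the list alone, which also called 1 higher), among them Dynlrb2, a dynein light chain, at -4.56 ± 0.75, the ciliary adenylate kinase Ak7 at -4.36 ± 0.44 and Foxj1, the transcription factor of motile cilia, at -3.21 ± 0.24. The ciliated list had a camera adjusted p = 2.12e-20, but adjusted p = 0.0933 with an estimated correlation. Of 25 club and secretory cell genes, 12 were lower (12 adjusted over the list alone), among them the trefoil factor Tff2 at -4.28 ± 0.28, Gp2 at -4.26 ± 0.52, the transcription factor Foxa3 at -3.91 ± 0.58 and the gel-forming mucin Muc5b at -3.64 ± 0.42. The secretory list had a camera adjusted p = 2.49e-13, but adjusted p = 0.168 with an estimated correlation. Scgb1a1 was not among them, at -0.10 ± 0.16 (adjusted p = 0.774). Of 11 submucosal gland genes, 5 were lower (5 adjusted over the list alone), with Dmbt1 at -2.78 ± 0.32 and Azgp1 at -2.26 ± 0.34. The gland list had a camera adjusted p = 4.6e-05, but adjusted p = 0.117 with an estimated correlation. Of 12 brush cell genes, 4 were lower (6 adjusted over the list alone), with Alox5ap of leukotriene synthesis at -2.58 ± 0.42 and the cation channel Trpm5 at -2.40 ± 0.47. The brush cell list had a camera adjusted p = 0.0015, but adjusted p = 0.354 with an estimated correlation. Of 11 neuroendocrine genes, 2 were lower (4 adjusted over the list alone), Uchl1 at -1.21 ± 0.23 and Snap25 at -1.77 ± 0.41. The neuroendocrine list had a camera adjusted p = 0.0016, but adjusted p = 0.129 with an estimated correlation. Both lay under background in the GFP+ gate, so they were at least 1.80-fold and 1.43-fold lower, and the call of Snap25 was lost without GFP+ replicate 3, which left 1 gene.

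**Figure D2:**
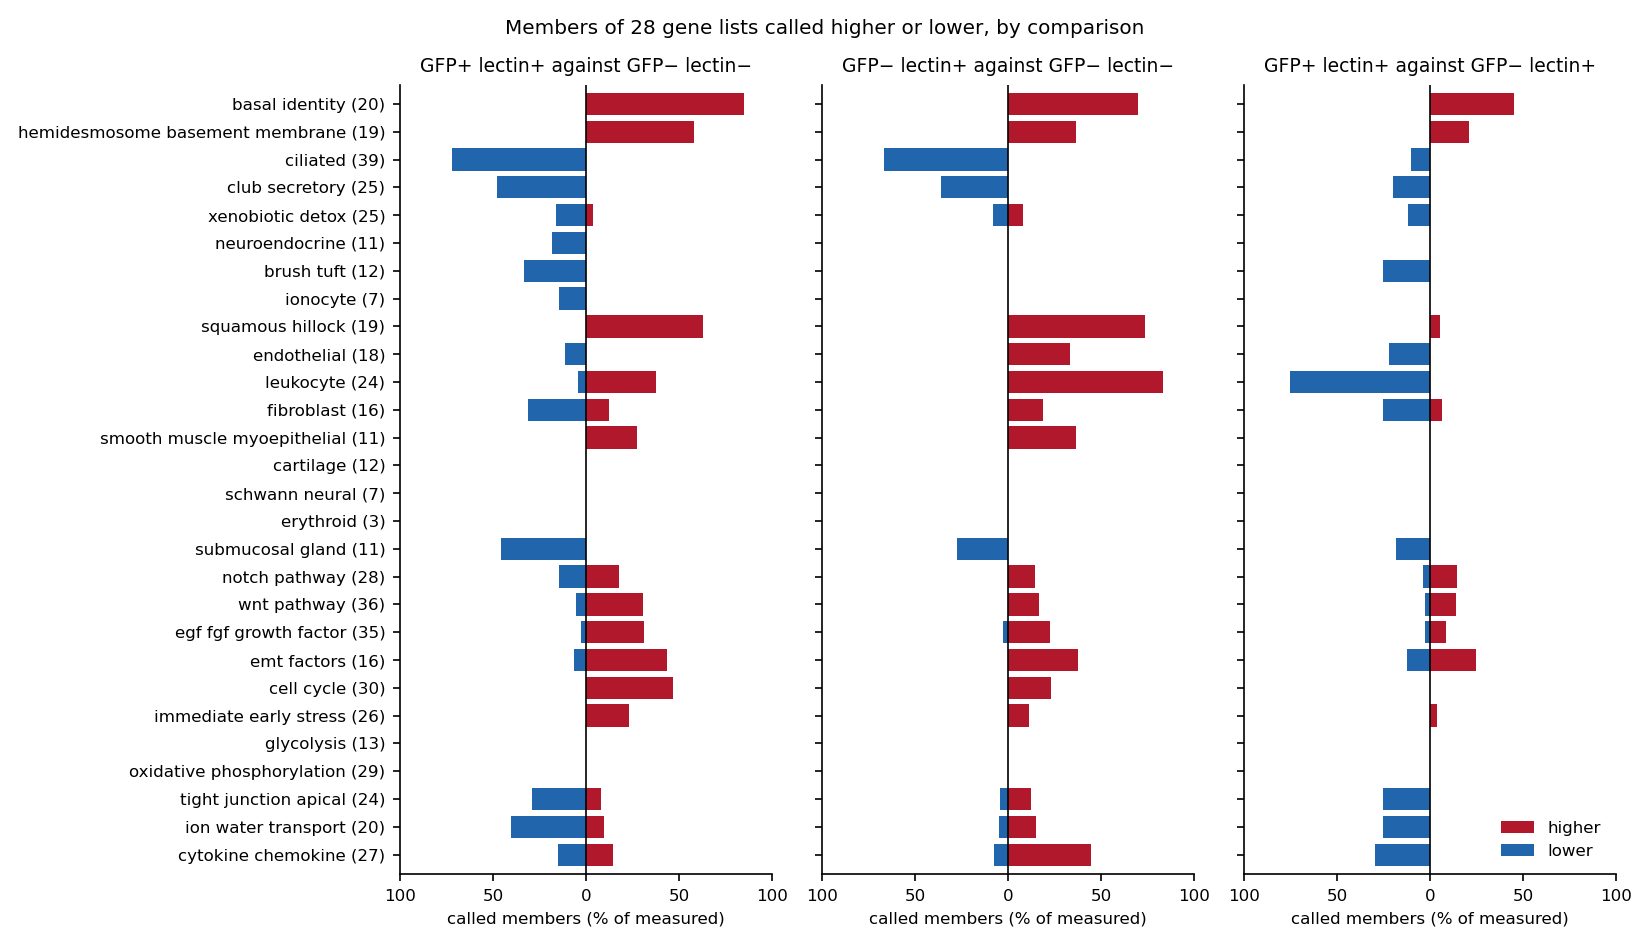
Share of the measured members of 28 gene lists (number measured in brackets) called higher (right, red) or lower (left, blue), in percent, for each of 3 comparisons of gates (panels). Of the basal cell list, 17, 14 and 9 of 20 genes were called higher from the left to the right panel, and of the leukocyte list 20 of 24 were called higher in the lectin-only against the columnar gate and 18 lower in the GFP+ against the lectin-only gate.

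Several signalling lists held called genes. In the Notch list of 28, 5 genes were higher and 4 lower (5 and 4 adjusted over the list alone), with the ligands Jag2 and Dll1 at 5.50 ± 0.22 and 4.61 ± 0.26, Dlk2 at 4.80 ± 0.29 and the receptor Notch1 at 2.31 ± 0.20. The list's median was -0.02 and its mean 0.53, and the list as a whole did not pass (camera adjusted p = 0.136), although it did with fry (adjusted p = 0.0073). The lower count in the Notch list fell to 2 without columnar replicate 1 or 3, lectin-only replicate 1 or GFP+ replicate 1, and to 1 without columnar replicate 2. In the Wnt list of 36, 11 genes were higher and 2 lower (11 and 2 adjusted over the list alone), with the ligand Wnt10a at 5.24 ± 0.20 and the secreted Wnt antagonist Sfrp1 at 5.10 ± 0.41 higher and the ligand Wnt5a at -3.64 ± 0.48 lower. The Wnt list had a camera adjusted p = 0.0014, but adjusted p = 0.203 with an estimated correlation. Without columnar replicate 2 or 3 or GFP+ replicate 3, 1 Wnt gene was lower. In the growth factor list of 35, 11 genes were higher and 1 lower (11 and 1 adjusted over the list alone), with Bmp7 at 4.82 ± 0.38, Igfbp2 at 4.37 ± 0.41 and the EGF-family ligand Nrg1 at least 14.2-fold higher. The growth factor list had a camera adjusted p = 0.0011, but adjusted p = 0.175 with an estimated correlation. In the list of epithelial-mesenchymal transition factors, 7 of 16 were higher and 1 lower (7 and 1 adjusted over the list alone), with Snai2, Tgfbi and Sparc (3.24 ± 0.23) higher. The transition factor list had a camera adjusted p = 9.1e-04, but adjusted p = 0.184 with an estimated correlation. Of 30 cell cycle genes, 14 were higher (23 adjusted over the list alone), with Cenpf at 2.36 ± 0.43, Mcm3 at 1.90 ± 0.30 and Kif11 at 1.87 ± 0.29. The cell cycle list had a camera adjusted p = 7.58e-12, but adjusted p = 0.175 with an estimated correlation. Of 26 immediate early genes, 6 were higher (6 adjusted over the list alone), with Myc at 3.51 ± 0.27 and Fosl1 at 1.86 ± 0.21. The immediate early list had a camera adjusted p = 5.4e-04, but adjusted p = 0.231 with an estimated correlation.

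Among genes of the apical surface and of transport, more were called lower than higher. Of 24 tight junction and apical genes, 7 were lower, 2 higher and 15 did not pass (7 lower and 2 higher adjusted over the list alone), with Cldn10 at -2.20 ± 0.22 and the membrane mucin Muc16 at -2.11 ± 0.39 lower and Cldn1 at 2.43 ± 0.25 higher. The junction list had a camera adjusted p = 0.0028, but adjusted p = 0.354 with an estimated correlation. Of 20 ion and water transport genes, 8 were lower, 2 higher and 10 did not pass (8 lower and 3 higher adjusted over the list alone), with the sodium channel subunit Scnn1b at -3.12 ± 0.53 and the potassium channel Kcnq1 at -2.29 ± 0.27 lower and the water channel Aqp3 at 3.06 ± 0.30 higher. The transport list had a camera adjusted p = 0.0047, but adjusted p = 0.289 with an estimated correlation. Without columnar replicate 2 or 3 or GFP+ replicate 2 or 3, 1 transport gene was higher. Of 25 detoxification genes, 4 were lower and 1 higher (6 and 1 adjusted over the list alone), with the monooxygenase Fmo1 at -3.06 ± 0.27 and the carboxylesterase Ces1f at -2.60 ± 0.24 lower and Cyp2s1 at 1.38 ± 0.22 higher. The detoxification list had a camera adjusted p = 0.0041, but adjusted p = 0.231 with an estimated correlation. The higher count was 2 without GFP+ replicate 1.

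Markers of cells other than epithelium were mixed in this comparison. Of 24 leukocyte genes, 9 were higher and 1 lower in the GFP+ gate (11 and 1 adjusted over the list alone), with S100a8 at 2.79 ± 0.37 and S100a9 at 2.89 ± 0.60. The leukocyte list had a camera adjusted p = 9.0e-04, but adjusted p = 0.410 with an estimated correlation and 0.0930 with fry. The leukocyte count fell to 5 without lectin-only replicate 3, to 4 without columnar replicate 1, lectin-only replicate 1 or GFP+ replicate 2, and to 3 without columnar replicate 2 or GFP+ replicate 3. In the fibroblast list of 16, the collagen genes Col3a1 at -3.88 ± 0.44 and Col1a2 at -3.36 ± 0.51 were among 5 lower genes, while the proteoglycan Dcn at 4.36 ± 0.21 and Fbln1 at 3.37 ± 0.42 were higher (6 and 2 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0599), although it did without columnar replicate 3, lectin-only replicate 2 or GFP+ replicate 3. Without GFP+ replicate 1 or 2, 3 fibroblast genes were lower. Of 11 smooth muscle and myoepithelial genes, 3 were higher (3 adjusted over the list alone), with the myosin kinase Mylk at 3.79 ± 0.63. The smooth muscle list had a camera adjusted p = 0.0425, but adjusted p = 0.354 with an estimated correlation and 0.0918 with fry, and its call was lost without columnar replicate 1 or 2, lectin-only replicate 3 or GFP+ replicate 1. The cytokine list of 27 had 4 genes higher and 4 lower (4 and 4 adjusted over the list alone), among them the interleukin 1 receptor antagonist Il1rn at 3.05 ± 0.52 and the chemokines Ccl28 at -3.58 ± 0.46 and Cxcl15 at -3.14 ± 0.27, and did not pass (camera adjusted p = 0.964). Without GFP+ replicate 1, 9 cytokine genes were higher. The endothelial and ionocyte lists did not pass either (camera adjusted p = 0.797 and 0.512), with 2 of 18 and 1 of 7 genes called lower (1 and 1 adjusted over the list alone). The endothelial count was 0 without columnar replicate 2 or GFP+ replicate 1 or 2, and 1 without columnar replicate 1 or 3, lectin-only replicate 1 or GFP+ replicate 3. The ionocyte count was 0 without columnar replicate 1 or 3 or GFP+ replicate 2 or 3. Limma called 0 genes of the cartilage, Schwann cell, erythroid, glycolysis and oxidative phosphorylation lists, where 0 of 12, 2 of 7, 0 of 3, 4 of 13 and 2 of 29 had an unadjusted p under 0.05.

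The lectin-only gate was compared with the columnar gate to describe lectin-binding cells that lacked the reporter. Basal and squamous keratins were higher in it, with Krt16 at 5.99 ± 0.68, Krt14 at 5.32 ± 0.68 and Krt17 at 5.51 ± 0.65, as were Tgfbi at 6.12 ± 0.24 and the epidermal differentiation gene Krtdap at 6.34 ± 0.91. Its largest increases also included the chemokine Ccl3 at 7.47 ± 0.81 (178-fold, adjusted p = 4.4e-04), interleukin 1 beta, Il1b, at 6.50 ± 0.38, the complement gene C1qb at 6.32 ± 1.10 and Cd83, a surface protein of dendritic cells, at 5.80 ± 0.68. The largest decreases included Ldb3 at -5.05 ± 0.61, the sulfotransferases Sult1c2 at -4.36 ± 0.41 and Sult1c1 at -4.23 ± 0.55, Cdh26 at -4.24 ± 0.38 and the amine oxidase Aoc1 at -4.24 ± 0.40. In all, 1610 genes were called, 1177 higher and 433 lower (73.1% higher), and 309 and 36 of them differed by at least 8-fold. The split depended on the scaling: it was 974 higher and 699 lower with arrays centred on their medians, 1036 and 587 after a further quantile normalization, and 928 and 489 without lectin-only replicate 3. The median difference over all genes was 0.07 as deposited and -0.17 with arrays centred.

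Of 24 leukocyte genes, 20 were higher in the lectin-only than in the columnar gate (20 adjusted over the list alone), among them Ptprc, the leukocyte common antigen, at 5.70 ± 0.58 (5.13 with dim arrays set to the background level), the proteoglycan Srgn at 5.48 ± 0.54 and the MHC class II genes H2-Ab1 at 5.42 ± 0.52 and H2-Aa at 5.38 ± 0.66. The leukocyte list had a camera adjusted p = 6.85e-21, but adjusted p = 0.0951 with an estimated correlation. Of 27 cytokine genes, 12 were higher and 2 lower (13 and 2 adjusted over the list alone), with Il1b and Il1a (3.63 ± 0.49) higher. The cytokine list had a camera adjusted p = 0.0011, but adjusted p = 0.237 with an estimated correlation. The lower cytokine count was 1 without any columnar array, lectin-only replicate 1 or 2 or GFP+ replicate 2 in turn. Of 18 endothelial genes, 6 were higher (8 adjusted over the list alone), with the receptor Tek at 2.48 ± 0.45 and the tight junction gene Cldn5 at least 2.27-fold higher. The endothelial list had a camera adjusted p = 1.0e-04, and adjusted p = 0.0473 with an estimated correlation. The endothelial count was 3 without columnar replicate 1, lectin-only replicate 1 or GFP+ replicate 3. Of 11 smooth muscle and myoepithelial genes, 4 were higher (5 adjusted over the list alone), with Acta2, smooth muscle actin, at 3.26 ± 0.53 and Mylk at 3.11 ± 0.63. The smooth muscle list had a camera adjusted p = 0.0011, but adjusted p = 0.196 with an estimated correlation. That count was 2 with arrays centred, and without columnar replicate 1 or 2, lectin-only replicate 1 or GFP+ replicate 3.

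Basal cell genes were higher in the lectin-only than in the columnar gate in 14 of 20 cases (14 adjusted over the list alone), among them Trp63 at 4.32 ± 0.20 and Ngfr at 2.53 ± 0.24. The basal list had a camera adjusted p = 2.70e-16, and adjusted p = 0.0074 with an estimated correlation. As above, this list is not independent evidence. Hemidesmosome and basement membrane genes were higher in 7 of 19 cases (7 adjusted over the list alone), with Col17a1 at 4.90 ± 0.43 and Lamb3 at 3.74 ± 0.32. The hemidesmosome list had a camera adjusted p = 6.79e-07, and adjusted p = 0.0152 with an estimated correlation. Squamous genes were higher in 14 of 19 cases (15 adjusted over the list alone), with the transglutaminase Tgm3 at 5.16 ± 0.96, Sprr3 of the cornified envelope at 5.01 ± 0.92 and Krt6a at 4.98 ± 0.98. The squamous list had a camera adjusted p = 1.03e-12, but adjusted p = 0.0951 with an estimated correlation. Ciliated cell genes were lower in 26 of 39 cases (28 adjusted over the list alone), with Dnah9, a ciliary dynein heavy chain, at -3.28 ± 0.60, Cdhr3 at -3.11 ± 0.48 and Foxj1 at -1.86 ± 0.24. The ciliated list had a camera adjusted p = 3.38e-21, but adjusted p = 0.0926 with an estimated correlation. Club and secretory genes were lower in 9 of 25 cases (9 adjusted over the list alone), with Tff2 at -2.35 ± 0.28. The secretory list had a camera adjusted p = 6.19e-10, but adjusted p = 0.195 with an estimated correlation. Without columnar replicate 2 or 3 or lectin-only replicate 1 or 2, 4 secretory genes were lower. Cell cycle genes were higher in 7 of 30 cases (11 adjusted over the list alone), with Cenpf at 2.25 ± 0.43 and Ccnb2 at 1.47 ± 0.29. The cell cycle list had a camera adjusted p = 7.24e-06, but adjusted p = 0.289 with an estimated correlation. The cell cycle count was 4 with arrays centred, and without columnar replicate 1 or lectin-only replicate 1 or 2, and 11 without columnar replicate 2.

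Factors of epithelial-mesenchymal transition were higher in the lectin-only gate in 6 of 16 cases (6 adjusted over the list alone), with Vim, the intermediate filament vimentin, at 3.35 ± 0.49, Snai2 at 3.35 ± 0.30 and Zeb2 at 2.74 ± 0.37. Vim and Zeb2, like 18 of the 24 leukocyte genes, were also higher than in the GFP+ gate, while Snai2 was lower than there. The transition factor list had a camera adjusted p = 3.6e-04, but adjusted p = 0.175 with an estimated correlation. In the Wnt list 6 of 36 were higher (7 adjusted over the list alone), with Sfrp1 at 2.99 ± 0.41, Wnt10a at 2.51 ± 0.20 and Wnt4 at 2.38 ± 0.27. The Wnt list had a camera adjusted p = 0.0248, but adjusted p = 0.331 with an estimated correlation. In the growth factor list 8 of 35 were higher and 1 lower (9 and 1 adjusted over the list alone), with the EGF-family ligand Ereg at 4.65 ± 0.67. The growth factor list had a camera adjusted p = 0.0248, but adjusted p = 0.259 with an estimated correlation, and that list's call was lost without lectin-only replicate 1. In the Notch list 4 of 28 were higher (4 adjusted over the list alone), with Jag2 at 3.12 ± 0.22 and Notch1 at 1.79 ± 0.20, and the list did not pass (camera adjusted p = 0.0998), although it did with fry (adjusted p = 0.0225).

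The GFP+ gate was compared with the lectin-only gate, since the labels call both basal cells and only the reporter separates them. Dlk2, a Delta-like protein, was higher in the GFP+ gate at 3.55 ± 0.29 (11.7-fold, adjusted p = 3.5e-04), as were Plcxd1 at 3.63 ± 0.47, Camk4, a calmodulin-dependent kinase, at 3.29 ± 0.46, Nrg1 at 3.06 ± 0.40, Dll1 at 2.89 ± 0.26, Larp6 at 2.82 ± 0.30 and Wnt10a at 2.73 ± 0.20. Other probe sets of Plcxd1, Larp6 and Camk4 lay at -0.11, -0.17 and -0.19 and were not called, whereas both probe sets of Dlk2 were. The largest decreases included Mmp12 and Fcgr2b. Mmp12, macrophage elastase, was at least 16.5-fold lower, and Fcgr2b, an Fc receptor, at least 13.8-fold lower. Cd83 at -4.57 ± 0.68, Itgax at -4.27 ± 0.35, the mannose receptor Mrc1 at -4.27 ± 0.40 and Il1b at -4.13 ± 0.38 were lower, as was Retnla at -4.72 ± 0.56. Ccl3 was lower at -4.68 ± 0.81, a call lost without lectin-only replicate 1 or 3. Trp63 was higher at 1.12 ± 0.20 (adjusted p = 0.0138), but not past the threshold without GFP+ replicate 1 (1.05, adjusted p = 0.0630), while Krt14 did not differ by the test (0.02 ± 0.68, adjusted p = 0.996). In all, 680 genes were called, 163 higher and 517 lower in the GFP+ gate, and 5 and 82 of them differed by at least 8-fold. The count fell to 373 without GFP+ replicate 1 (85 higher and 288 lower), and the higher count fell to 96 without lectin-only replicate 1. The split was 256 higher and 457 lower with arrays centred, 230 and 456 after a further quantile normalization, and 163 and 310 without lectin-only replicate 3, and the median difference over all genes was -0.10 as deposited and 0.06 with arrays centred.

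Of 24 leukocyte genes, 18 were lower in the GFP+ than in the lectin-only gate (19 adjusted over the list alone), with Tyrobp, a signalling adaptor of myeloid cells, at -3.82 ± 0.43, Coro1a at -3.81 ± 0.48 and Cd52 at -3.68 ± 0.29. The leukocyte list had a camera adjusted p = 1.68e-23, but adjusted p = 0.0926 with an estimated correlation. Of 27 cytokine genes, 8 were lower (14 adjusted over the list alone), with Ccl2 at least 7.14-fold lower and Cxcl2 at -2.59 ± 0.31. The cytokine list had a camera adjusted p = 3.27e-07, but adjusted p = 0.138 with an estimated correlation. Of 18 endothelial genes, 4 were lower (7 adjusted over the list alone), with Vwf, von Willebrand factor, at -2.03 ± 0.29. The endothelial list had a camera adjusted p = 1.50e-07, and adjusted p = 0.0149 with an estimated correlation. The endothelial count was 2 with arrays centred or without GFP+ replicate 2 or 3, and 1 without lectin-only replicate 1. Of 16 fibroblast genes, 4 were lower and 1 higher (6 and 1 adjusted over the list alone), with Col3a1 at -3.52 ± 0.44 and Col1a1 at -3.20 ± 0.49. The fibroblast list had a camera adjusted p = 0.0041, but adjusted p = 0.202 with an estimated correlation, and the list's call was lost without lectin-only replicate 1. Of 16 factors of epithelial-mesenchymal transition, 4 were higher and 2 lower (5 and 3 adjusted over the list alone), with Snai2 at 2.49 ± 0.30 and Sparc at 1.54 ± 0.23 higher and Zeb2 at -3.07 ± 0.37 and Vim at -2.91 ± 0.49 lower, and the list did not pass (camera adjusted p = 0.0748). Without lectin-only replicate 1 or 2 or GFP+ replicate 1 or 2, 2 of these factors were higher.

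Basal cell genes were higher in the GFP+ than in the lectin-only gate in 9 of 20 cases (9 adjusted over the list alone), with Dlk2, Snai2 and Jag2 (2.39 ± 0.22) among them. The basal list had a camera adjusted p = 1.58e-17, and adjusted p = 0.0074 with an estimated correlation. Without GFP+ replicate 1, 4 basal cell genes were higher. Here too the basal list is not independent evidence. Hemidesmosome and basement membrane genes were higher in 4 of 19 cases (4 higher and 1 lower adjusted over the list alone), with Lamb3 at 2.08 ± 0.32 and the integrin Itgb4 at 1.49 ± 0.23. The hemidesmosome list had a camera adjusted p = 6.57e-09, and adjusted p = 0.0096 with an estimated correlation. Without lectin-only replicate 1 or GFP+ replicate 1, 2 hemidesmosome genes were higher. Club and secretory genes were lower in 5 of 25 cases (8 adjusted over the list alone), with Tff2 at -1.93 ± 0.28 and Creb3l1 at -1.66 ± 0.19. The secretory list had a camera adjusted p = 3.55e-07, but adjusted p = 0.239 with an estimated correlation. Without GFP+ replicate 1, 2 secretory genes were lower, and without GFP+ replicate 2, 8 were. Tight junction and apical genes were lower in 6 of 24 cases (8 adjusted over the list alone), with Cldn4 at -1.36 ± 0.22. The junction list had a camera adjusted p = 8.96e-08, but adjusted p = 0.175 with an estimated correlation. This count was 1 without lectin-only replicate 3, 2 without lectin-only replicate 1 or GFP+ replicate 1, and 3 without GFP+ replicate 3 or with arrays centred. Brush cell genes were lower in 3 of 12 cases (5 adjusted over the list alone), with Alox5ap at -2.93 ± 0.42 and Sh2d6 at -1.90 ± 0.27. The brush cell list had a camera adjusted p = 9.4e-06, but adjusted p = 0.231 with an estimated correlation. Limma called 0 of 30 cell cycle genes, where 1 had an unadjusted p under 0.05, and the list's median was 0.38. The cell cycle list had a camera adjusted p = 3.63e-07, but adjusted p = 0.240 with an estimated correlation and 0.215 with fry.

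Calls of both lectin-binding gates against the columnar gate were then intersected, to ask which changes they had in common. They shared 1011 genes called in the same direction, 606 higher and 405 lower, where independent lists would share 69.2 and 23.1. In 20 runs with all 9 arrays simulated without differences between gates, 0 genes were shared. Groups without differences give few calls to share, so this 0 was nearly fixed in advance. It does not measure how much of the overlap comes from sharing the columnar arrays. Log2 differences of the 2 comparisons had a correlation of 0.770 across genes, which are not independent replicates, against 0.50 in the simulation. Their covariance was 0.594 against 0.0451, a difference of 0.549. The 3 columnar arrays cannot be split into 2 parts of at least 2 arrays each, so some of the overlap may come from sharing them. Of the genes called in the lectin-only gate, 51.5% of the higher and 93.5% of the lower ones were shared, and 1 gene, the chemokine Ccl9, was called in opposite directions (-1.18 in the GFP+ gate and 1.46 in the lectin-only gate). Shared higher genes held 14 of 20 basal cell genes where 0.67 would fall by chance (Fisher's exact test, adjusted p = 1.6e-15), 11 squamous genes (adjusted p = 6.4e-11), 9 of 24 leukocyte genes where 0.80 would fall by chance (adjusted p = 5.6e-07) and 7 hemidesmosome genes (adjusted p = 1.9e-05). They also held 8 growth factor genes, 7 cell cycle, 6 Wnt, 4 transition factor and 3 smooth muscle genes, each above chance (adjusted p between 1.4e-04 and 0.0278). Without 1 array the squamous count fell to 5 (columnar replicate 1 or 2 or GFP+ replicate 3) or 6 (GFP+ replicate 2). The leukocyte count fell to 3 (columnar replicate 2 or GFP+ replicate 3), 4 (columnar replicate 1, lectin-only replicate 1 or GFP+ replicate 2) or 5 (lectin-only replicate 3). The cell cycle count was 4 without columnar replicate 1 or lectin-only replicate 1 or 2 and 11 without columnar replicate 2, and the smooth muscle count was 1 without columnar replicate 2 or GFP+ replicate 1. Tgfbi, Tpm2, Cd109, Duoxa1 and Lgals7 were among the largest, with Cd109 at 6.64 ± 0.23 and 5.72 ± 0.23 in the 2 gates. Shared lower genes held 26 of 39 ciliated cell genes where 0.87 would fall by chance (Fisher's exact test, adjusted p = 2.6e-32), 9 club and secretory genes and 3 gland genes. The secretory count fell to 4 without columnar replicate 2 or 3 or lectin-only replicate 1 or 2. The gland count fell to 0 without columnar replicate 2 or lectin-only replicate 1 or 2, and to 1 without columnar replicate 3 or lectin-only replicate 3. Fisher's test treats genes as independent, and of these lists the basal and hemidesmosome lists alone passed in both comparisons with an estimated correlation, the others having adjusted p between 0.0926 and 0.410. The basal list holds Krt5 and markers put forward from sorted cells of this kind, so its overlap is not independent evidence. The shared split was 504 higher and 594 lower with arrays centred, and 533 and 519 after a further quantile normalization.

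**Figure D3:**
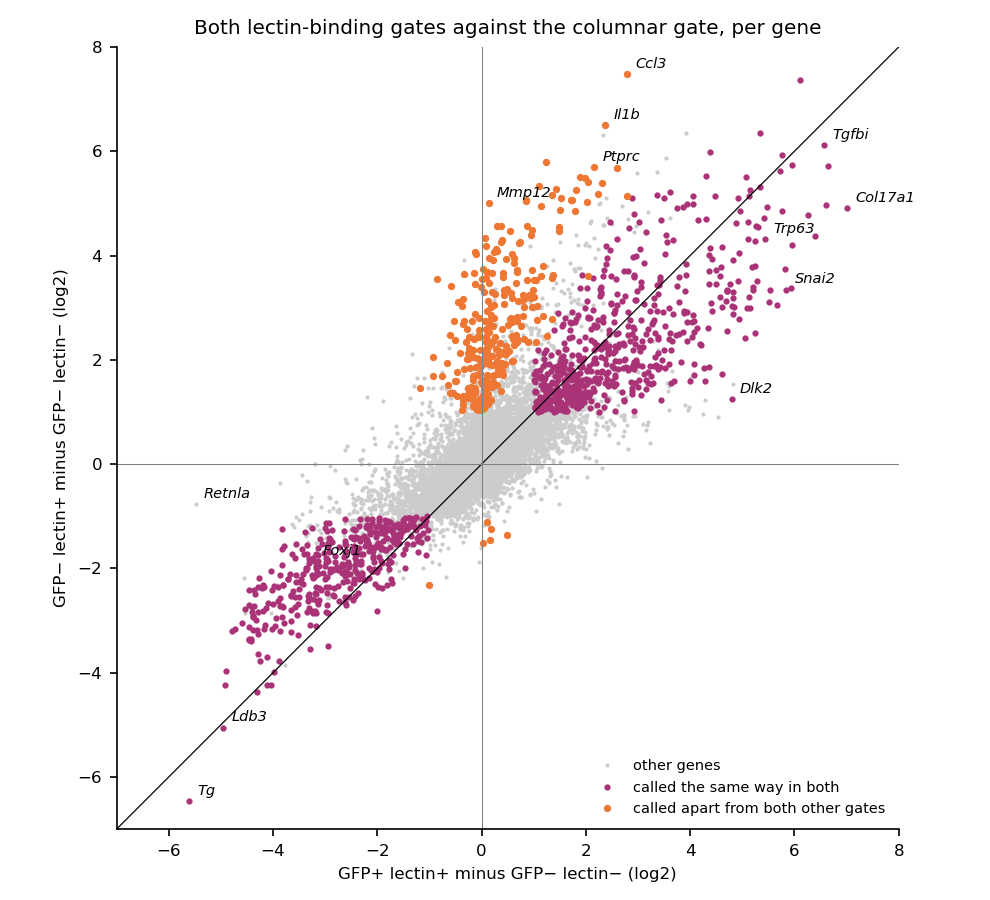
Log2 difference from the columnar gate of each of 18193 genes (points) in the GFP+ gate (horizontal axis) and in the lectin-only gate (vertical axis), with the line of equal differences. Purple points are genes called the same way in both gates and orange points those called apart from both other gates, including 20 that also belong to the shared set. Cd109 lies at 6.64 and 5.72, and Snai2 at 5.84 and 3.35.

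Genes called in the same direction in the lectin-only gate against both other gates were set apart, since a mixture of the other two gates would not place a gene beyond both. They numbered 292, of which 286 were higher and 6 lower in the lectin-only gate, where independent lists would share 33.4 and 3.88. Both comparisons use the same lectin-only arrays, so part of the overlap may come from sharing them. In 20 simulations of unchanged groups 0 genes were set apart, which was nearly fixed in advance since such groups give few calls. In 20 simulations that kept each gene's lectin-only mean between those of the other gates, a mean of 4.10 and at most 11 genes were set apart as higher, and a mean of 1.75 and at most 5 as lower. The 286 genes made up 24.3% of the genes higher in the lectin-only than in the columnar gate. The largest by the smaller difference were Mmp12, Ccl3, Cd83, Itgax, Mrc1, Ccl4, C5ar1, Dock10, Ms4a7 and Il1b. Of the 24 leukocyte genes 18 were in the set where 0.38 would fall by chance (Fisher's exact test, adjusted p = 1.0e-26), and so were 6 cytokine genes (adjusted p = 3.4e-05) and 3 endothelial genes (adjusted p = 0.0158). With an estimated correlation the endothelial list passed in both comparisons, and the leukocyte and cytokine lists did not. The endothelial count fell to 0 without lectin-only replicate 1 or GFP+ replicate 3, and to 1 without columnar replicate 1 or GFP+ replicate 2. The count fell to 190 without GFP+ replicate 1 (189 higher and 1 lower), and the 6 lower genes fell to 2 without lectin-only replicate 2 or GFP+ replicate 3 and to 3 without GFP+ replicate 2.

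The position of the lectin-only gate between the other two was the share of each gene's difference between the GFP+ and columnar gates that the lectin-only gate showed, on the log2 scale and without a test. Its median was 0.703 over the 1069 higher genes and 0.584 over the 969 lower genes. Per array of the lectin-only gate the medians were 0.661, 0.632 and 0.860 for higher genes (SD 0.124, n = 3) and 0.632, 0.663 and 0.408 for lower genes (SD 0.139, n = 3), so the values of replicate 3 lay apart in both. With arrays centred the medians were 0.604 and 0.671, the other way round.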

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

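The tests of leukocytes inside the lectin-only gate, of the lectin-only gate as a mixture for the genes set apart, and of both explanations for the secretory transcripts were chosen after the results were seen. Signals outside the gene comparisons were looked at because no comparison of the report uses them. The poly-A spike-in control probe sets were 1.59 higher on the log2 scale in the columnar gate than on the 6 lectin-binding arrays, with means of 7.73 ± 0.97 (SD, n = 3) in the columnar, 6.09 ± 0.46 in the lectin-only and 6.20 ± 0.44 in the GFP+ gate. All 3 columnar arrays lay above the other 6 (exact permutation test, two-sided, p = 0.0119 over 84 splits, and 0.131 after adjustment over 11 array measures). With 84 splits, 0.0119 is the smallest p this test can give. Adjustment over 11 measures turns that p into 0.131 unless other measures have low p-values too. The adjusted value therefore cannot decide whether the columnar arrays differ in this measure. Of 9160 probe sets with no gene symbol, which entered no gene count, 241 passed the same threshold in the GFP+ against the columnar gate, 157 higher and 84 lower.

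Transcripts of leukocytes were high in the lectin-only gate: 18 of the 24 leukocyte genes were higher there than in both other gates, with a median of 3.35 log2 above the GFP+ gate. An upward shift of lectin-only replicate 3 as the whole source is excluded, since the excess was 3.14 without that array. Leukocytes inside the gate fit the values, as a hypothesis: Cd74 had a mean log2 signal of 12.58, H2-Ab1 11.89, H2-Aa 11.66 and Laptm5 11.39, and the labels name no gate on a leukocyte antigen that would remove such cells, although 20 of the 24 genes were also above background in the columnar gate, 1 (Lyz2) stands in another list, and Cd3e, Lyz2, Itgam, Cd79a, Cd79b and S100a9 were not higher than in both gates. Of the lymphoid genes Cd3e, Cd3g, Cd79a and Cd79b only Cd3g was higher than in both, so the values say little about lymphoid cells. Expression of these genes by epithelial cells of the gate cannot be told apart from leukocytes on bulk arrays; on GFP+ replicate 3 the leukocyte list lay 1.04 above the other 2 arrays of its gate and the basal list at -0.19, which rests on 1 array. A biological explanation inside the design, that lectin-binding cells without the reporter are a distinct epithelial population, may account for part of the pattern and was not tested.

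For the 286 genes set apart as higher in the lectin-only gate, a mixture of GFP+ and columnar cells is excluded, since 24.3% of the genes higher than in the columnar gate lay above both other gates, where simulations with the lectin-only mean between the others set apart at most 11. For the 6 set apart as lower it is not excluded, since those simulations set apart up to 5. For the position of the lectin-only gate between the others, such a mixture stays open. The linear mixing shares from genes high and genes low in the GFP+ gate differed by 0.33, 0.40 and -0.10 on the 3 arrays, the smallest size being 0.097, and by 0.49, 0.39 and 0.38 with arrays centred. The deposited scaling of replicate 3 decides whether the shares of that array differ, so a mixture and a distinct population cannot be told apart for these genes.

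Some abundant secretory transcripts had nearly the same signal in the GFP+ as in the columnar gate, such as Scgb1a1 with 93.1% and Bpifa1 with 94.9% of the columnar signal. Others fell, such as Bpifb1 to 24.7% and Muc5b to 9.63%, and Bpifa1 and Bpifb1 were chosen as examples after their values were seen. Carry-over of columnar RNA alone, in an even share, would leave secretory genes about the same share of their columnar signal. The 16 above log2 13 in the columnar gate kept a median of 70.8% in the GFP+ gate, against 11.7% for the other 9. Tff2, at 10.95 in the columnar gate, kept 5.25%, and Gabrp, at 12.88, kept 59.5%. Without compression, even carry-over would not give medians this far apart. Compression above log2 13 was not excluded, so the shares there do not decide whether carry-over is their source. Carry-over together with compression stays open, since near the top of the scale shares measure RNA only if signals are not compressed. Such compression may contribute and stays open too, since 5 of the 16 secretory genes above log2 13 fell by over 1 and the others did not. No gene of the ciliated list entered this test. How much carry-over and compression each add cannot be told apart here. No biological explanation was tested.

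Other splits of the arrays were counted for each result. For the 3 comparisons of gates, 1 of 10 splits, the real one, gave as many genes (2038, 1610 and 680, where the highest other split gave 0), and 10 splits are too few for a share under 0.05. For the shared genes, 1 of 100 splits into 3 groups gave as many, with 1011 in the real split and 143 in the highest other. For the genes set apart, 2 of 100 splits gave as many as the real 292. The other was a split with 731 genes whose middle group held the 3 columnar arrays, so it follows the structure of the samples, and the next highest gave 153. Both shares are under 0.05, which speaks against gate labels that bear no relation to the signals. They decide no more than that. Most other splits put arrays of different gates into 1 group, which widens the spread within groups and lowers their counts.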

How the results depend on the processing

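Of the alternatives, only centring together with leaving out lectin-only replicate 3 was chosen after seeing the data. It called 2101, 1489 and 469 genes for GFP+ against columnar, lectin-only against columnar and GFP+ against lectin-only, and left 1008 shared and 197 set apart. Counts of genes kept within 1.5 times of the reported value under the settings not named here. With probe sets in place of genes, 3153 were called in GFP+ against columnar. At an adjusted p under 0.01, 1027 were called in lectin-only against columnar and 261 in GFP+ against lectin-only, with 616 shared and 137 set apart. A test against a 1.5-fold change (treat) called 1135, 893 and 208, with 520 shared and 128 set apart. Both are stricter thresholds on the same fit. With 1 array left out, the 3 counts ranged from 1687 to 2070, 1343 to 1634 and 373 to 633, the shared genes from 805 to 1083 and the genes set apart from 190 to 310. The lowest values of 373 and 190 came without GFP+ replicate 1, and each such fit has fewer arrays. The position of the lectin-only gate ranged from 0.634 to 0.752 for higher and from 0.521 to 0.666 for lower genes, and the number of called lists from 17 to 19, 15 to 16 and 15 to 19. With an estimated correlation between genes, camera called 2, 3 and 3 lists, and the cause of the losses was not tested. A higher correlation is not the whole reason. The hemidesmosome list had an estimate of -0.021, under the preset 0.01. Its adjusted p in GFP+ against columnar still rose from 8.54e-12 to 0.0074 in camera. For the endothelial list, with an estimate of 0.0023, the camera adjusted p in lectin-only against columnar rose from 1.0e-04 to 0.0473. A higher adjusted p with that setting therefore does not by itself show correlation between the genes of a list.

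Without probe sets marked s, x or a, 3 named genes changed sign in GFP+ against columnar, at -0.024 for Lama3, -0.064 for Ptprc and -0.19 for Acta2, because the remaining probe set of each gene is another one. Over 7942 results of named genes under all alternatives, 7307 kept their direction and side of the threshold, 614 were no longer past it, 18 passed it newly and those 3 reversed. Of 309 named calls, 237 held with each array left out: 98 of 111, 91 of 113 and 48 of 85 in the 3 comparisons. With a replicate block, 2193, 1785 and 906 genes were called, with 1134 shared and 366 set apart, and the counts of lists stayed at 18, 16 and 16. The replicate numbers did not meet the rule for pairing: the correlations of same-numbered arrays ran from -0.07 to 0.33, with 4 of 9 pairs over 0.1, although 7 of 9 arrays correlated best with their own number. Signal over background limits the rest: the dimmer gate was under background in 137, 190 and 87 called results, where only bounds on the fold can be given.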

Other observations

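The test of thyroid genes was run on a list chosen after thyroglobulin was seen among the called genes, and the genes named in the next paragraph were also chosen after their values were seen. Some transcripts of rare cells stood high on 1 columnar array alone. Grp, the gastrin-releasing peptide of neuroendocrine cells, had a log2 signal of 7.51 on columnar replicate 1, against 2.52 and 2.46 on the other two arrays of the gate. Scg2, secretogranin, had 7.46 there against 5.11 and 3.71. Dcpp1, a salivary and gland protein, had 7.66 on columnar replicate 3 against 2.55 and 2.71. None of these 3 was called in a comparison.

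The leukocyte genes also varied within the GFP+ gate. On GFP+ replicate 3, 19 of the 24 genes had the highest signal of the gate, against 1 on replicate 1 and 4 on replicate 2, while the basal list differed by -0.19 from the other two arrays.

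Thyroglobulin, Tg, had log2 signals of 13.02, 6.45 and 9.47 on the 3 columnar arrays and 6.12 or less on the others. Iyd, the iodotyrosine deiodinase, had 9.54, 7.13 and 7.19 on the columnar arrays. The thyroid lies next to the trachea, so thyroid tissue in the dissected sample may be a source of these transcripts, as a hypothesis. If so, other thyroid genes should be above background and higher there: on average 2 of 6 were (Slc5a5 and Dio1), and Tshr, Pax8, Hhex and Tff3 were not. By limma, Slc5a5 did not pass against the GFP+ or lectin-only gate (adjusted p = 0.098 and 0.173). Dio1 passed against the GFP+ gate (0.034) but not the lectin-only gate (0.302). Dio1 lay at 7.04, 6.95 and 7.12 on the columnar arrays, so it did not follow Tg there. Slc5a5 lay at 7.34, 4.24 and 5.16 on these arrays, in the same order as Tg. The share lies between the bounds set beforehand, so the explanation stays open. The labels name no gate that would remove thyroid cells.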
